A study of Homo sapiens with 4 samples.

How the data were processed

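Gene expression was measured by 10x Visium HD in 4 formalin-fixed, paraffin-embedded sections of 1 soft tissue sarcoma, 1 for each time point T1 to T4. The authors counted UMIs with Space Ranger 4.0.1 against GRCh38 and assigned them to segments of a cell segmentation of the tissue image, and their notes also name Seurat. The deposited matrices hold raw UMI counts per gene and segment, which was checked on the values: all are whole numbers from 1 up. Each section came with 2 copies of its matrix, with 0 lines that differed, so 1 copy was used. Segment outlines were deposited in image pixels with a scale in micrometres per pixel, and areas and centres were computed from them. The probe set and the sequencing depth were not stated.

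The files held 18085 genes. The 16 genes that are Y-linked or XIST were left out of every step, which left 18069. Genes whose level can follow the genotype or a copy number change of 1 person were not named. The lists, the comparisons and the named-gene rule were chosen before the data were examined. UMIs of all segments of a section were summed per gene and divided by the section total to give CPM, with an exact Poisson 95% interval. The ratio of CPM between 2 sections had an exact conditional (Clopper-Pearson) 95% interval. Totals ran from 730295 UMIs in T1 to 38465640 in T2, so that a gene with no UMI could have had up to 4.11 CPM in T1, 0.0780 in T2, 0.0993 in T3 and 0.323 in T4 (3 counts of the total). With 1 section per time point from 1 person, no p-value was computed, and intervals cover counting error only.

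The 5 comparisons were T2 over T1, T3 over T2, T4 over T3, T3 over T1 and T4 over T1. Each of 37 gene lists was summarised by the median log2 ratio of CPM (prior count 0.5) over its genes with at least 20 UMIs in both sections together, with an interval from 1000 Poisson redraws of the counts. That median was set against 10000 random lists of as many genes, matched in 20 bins of mean expression, and its percentile among them describes these sections. Lists below percentile 2.5 or above 97.5 were said to stand apart. They covered interferon-stimulated genes, double-stranded RNA sensing, the interferon-gamma response, class I and class II presentation, p53 targets, proliferation, inflammation and NF-kB, senescence-associated secretion, matrix, hypoxia and glycolysis, checkpoints and exhaustion, tertiary lymphoid structures, complement, heat shock and immediate early genes, mitochondrially encoded genes and housekeeping genes. The other 20 held cell type markers, of T, cytotoxic, regulatory T, B and plasma cells, macrophages, lipid-associated macrophages, both kinds of dendritic cell, neutrophils, mast cells, endothelial and lymphatic endothelial cells, pericytes, fibroblasts, adipocytes, skeletal muscle, epithelium, Schwann cells and red blood cells. Some genes stood in more than 1 list, and the files lacked 9 of the 12 class II genes and 5 of the 18 class I genes.

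Genes were named by this rule. First, up to 10 genes per direction and comparison with at least 50 CPM in the higher section were taken by the interval bound nearest to a ratio of 1. Second, up to 4 members per list and comparison were taken by the same bound, with at least 20 UMIs in both sections together. Last, a gene so named could be followed through all sections. CXCL10 near and far from T cells, and the genes given within cluster classes, fall outside this rule and were chosen after their values were seen.

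Shares of segments with a UMI of a list were counted after each segment was thinned at random to 50 UMIs, with shallower segments left out, and had exact binomial (Clopper-Pearson) 95% intervals. The same share for as many olfactory receptor genes was set beside them as background. For clusters, segments with at least 50 UMIs were scaled to 1000 UMIs, log-transformed, reduced to 30 principal components of 2000 variable genes and clustered by the Leiden method at resolution 1 on 15 nearest neighbours. A cluster was named after a cell type when its 50 leading genes, each at 50 CPM or more and raised at least 2-fold over the other segments of the same section, held 3 markers of that type and the first 10 did not favour another type. A cluster whose median UMI count lay below its section's median divided by 3 stayed unnamed if its first 10 genes held no marker of the type. After the clusters were seen, a name was also made to require 100 other segments of the section, since 1 cluster held nearly all of T1. For distances, CPM in segments within 50 micrometres of a segment with a UMI of any of 7 T cell genes (CD3D, CD3E, CD3G, CD2, TRAC, TRBC1 and TRBC2) was divided by CPM beyond that distance, the marker segments themselves left out.

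Alternatives to these choices were TMM factors, median-of-ratios size factors, totals without mitochondrial genes and the 50 genes with most UMIs, thinning of the deeper section, only segments with at least 50 UMIs, a gene filter of 0 or 100 UMIs, a prior count of 2, each section without 1 quadrant of its area in turn, thinning to 100 or 200 UMIs or none, a minimum of 100 or 200 UMIs for clustered segments, resolution 0.5 and 2, and 25 and 100 micrometres. Added after seeing the data were subtraction of each section's median olfactory receptor level, a filter on genes with a mean of at least 50 CPM, distances without TRAC, and list medians within cluster classes.

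The steps were tested on simulated data made from the section totals. The 95% intervals held the set ratio for 96.2%, 95.5%, 95.6%, 96.3% and 96.4% of genes in the 5 comparisons in the order above. Per comparison 200 genes were raised, in equal parts 2-fold and 4-fold. Of those raised 2-fold, 78%, 93%, 96%, 78% and 76% had an interval that excluded no change. Of those raised 4-fold, 97%, 100%, 100%, 97% and 98% did. All 20 lists raised 1.5-fold stood above percentile 97.5, and 6, 3, 4, 6 and 4 of 100 unchanged lists lay outside the middle 95%. Both simulated sections shared 1 mean profile and differed only by counting noise and the set changes. Real sections differ in many genes, so these rates check the calculation. They do not tell how large a shift a real list needs to stand apart. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. Tissue images were not used here.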

Results

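The data were spatial expression profiles of 4 formalin-fixed sections of 1 soft tissue sarcoma, with 1 section for each of 4 time points. T1 was the untreated tumour. T2 followed 1 intratumoral dose of BO-112, a nanoplexed form of the double-stranded RNA mimic poly I:C, and preceded radiation. T3 followed 5 radiation fractions of 6 Gy and 2 doses of BO-112. T4 was the tumour at surgery, after the same radiation and 3 doses. Transcripts were counted as unique molecular identifiers (UMIs) in segments that outline single cells on the tissue image. T1 held 7915 segments and 730295 UMIs, T2 held 13427 segments and 38465640 UMIs, T3 held 17060 segments and 30196390 UMIs, and T4 held 9239 segments and 9299683 UMIs. The median segment held 88 UMIs in T1, 2611 in T2, 1474 in T3 and 813 in T4. There were no replicates, so no spread between samples of 1 time point could be estimated and no test was run. All intervals below are 95% intervals that cover counting error only, and each comparison describes these sections.

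Normally silent genes had higher levels in T1 than in the other sections. The 348 olfactory receptor genes, which serve odour sensing and are normally silent in soft tissue, had a median of 11 counts per 1000000 UMIs (CPM) in T1, against 0.234 in T2, 0.431 in T3 and 0.430 in T4. In T1, 55.4% of all genes lay below 3 times that median, against 23.3% in T2. The median gene of T2 over T1 had a log2 ratio of -0.28. Scaling by TMM moved that median by 0.45, by 0.35 in T3 over T1 and by 0.38 in T4 over T1, and by -0.10 in T3 over T2. List medians are therefore set beside random lists of genes of like expression, which any scaling moves alike.

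The first comparison, T2 over T1, asks what was different in the tumour after 1 dose of the RNA mimic. Macrophage genes, matrix genes and, by less, interferon-stimulated genes were higher in T2, and proliferation genes were lower than in random lists of like expression. Of the 19 macrophage and monocyte genes, 18 were higher in T2, with a median log2 ratio of 0.82 (0.66 to 1.14), above all 10000 random lists. They included the antibacterial enzyme gene LYZ (ratio 2.94, 2.16 to 4.10) and CD163, a scavenger receptor for haemoglobin complexes (3.35, 2.11 to 5.65). CD14, a co-receptor for bacterial lipopolysaccharide, had a ratio of 3.09 (2.00 to 5.07). The 12 lipid-associated macrophage genes had a median of 1.05 (0.79 to 1.61), with 11 higher. Among them were GPNMB (5.21, 4.46 to 6.13), the secreted phosphoprotein gene SPP1 (6.08, 3.62 to 11.1) and the lipid carrier gene APOE (3.75, 3.06 to 4.66). Among the genes with the highest ratios by the named-gene rule, the iron exporter SLC40A1 had a ratio of 4.16 (3.27 to 5.37) and the haem oxygenase HMOX1 a ratio of 4.46 (3.12 to 6.61).

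Matrix genes were higher together in T2. Of the 32 extracellular matrix genes, 29 were higher, with a median of 0.88 (0.80 to 0.96), above all 10000 random lists, and the 16 fibroblast genes had a median of 0.85 (0.78 to 0.99). Periostin (POSTN) stood at 408 CPM in T1 and 1510 in T2, a ratio of 3.69 (3.29 to 4.15). The collagen genes COL1A2 (2.5, 2.40 to 2.61) and COL3A1 (2.24, 2.19 to 2.29) were abundant in both sections, and the calcification inhibitor MGP had the highest ratio by the named-gene rule at 6.11 (4.52 to 8.48).

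Interferon-stimulated genes were higher in T2 by a small margin. Of 40, 26 were higher and 14 lower, with a median of 0.27 (0.11 to 0.37) against -0.02 for random lists, percentile 99.7, and without the quadrant of T1 at high x and low y the median was 0.15. The clearest were OAS2 (ratio 2.41, 1.61 to 3.76), which makes the second messenger that activates RNase L, TRIM22 (1.73, 1.31 to 2.36), IFI27 (1.56, 1.25 to 1.98) and UBE2L6 (1.54, 1.22 to 1.98), which conjugates ISG15. The value depended on the scale, at 0.72 with TMM, while its rank among random lists does not depend on scaling. The 14 genes of double-stranded RNA sensing had a median of -0.24 (-0.34 to -0.02), at percentile 13.1 of their random lists, and that median was 0.21 with TMM. Interferon-gamma response genes had a median of 0.03 (-0.23 to 0.17), with 13 higher and 12 lower. Within that list the ubiquitin-like UBD (0.133, 0.0796 to 0.236) and the T cell attractants CXCL11 (0.160, 0.0991 to 0.273) and CXCL9 (0.250, 0.165 to 0.396) were lower in T2, and their T1 levels of 23.3, 26.0 and 32.9 CPM all lay at or below 3 times the olfactory receptor median. Of 13 class I presentation genes 6 were higher and 7 lower, with B2M, the light chain of class I molecules, at 2.65 (2.43 to 2.90). The 3 class II presentation genes were all higher, with a median of 0.77 (0.52 to 0.99), percentile 97.2, within the middle 95% of random lists, and were led by the invariant chain gene CD74 (1.78, 1.59 to 2.01).

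Proliferation genes had a median of -0.46 (-0.56 to -0.34) in T2 over T1, below all 10000 random lists, with 35 of 42 lower. UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, had a ratio of 0.323 (0.266 to 0.395), and the survivin gene BIRC5 a ratio of 0.355 (0.275 to 0.466). With TMM the median was -0.01, so the level relative to other genes was lower but the level itself depended on the scale. T cell genes had a median of -1.19 (-1.46 to -0.75) and cytotoxic lymphocyte genes one of -0.69 (-1.04 to -0.31), neither outside the middle 95% of random lists. With the olfactory receptor median subtracted from each section, an alternative chosen after seeing the data, they were -0.036 and 0.48, again within it. The 11 mitochondrially encoded genes had a median of -1.70 (-1.74 to -1.65), all lower in T2. The 10 genes with the lowest ratios by the rule were led by TRIM64B (0.0101, 0.00750 to 0.0136) and LIPI (0.00927, 0.00523 to 0.0160), both below 2 CPM in T2.

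**Figure D1:**
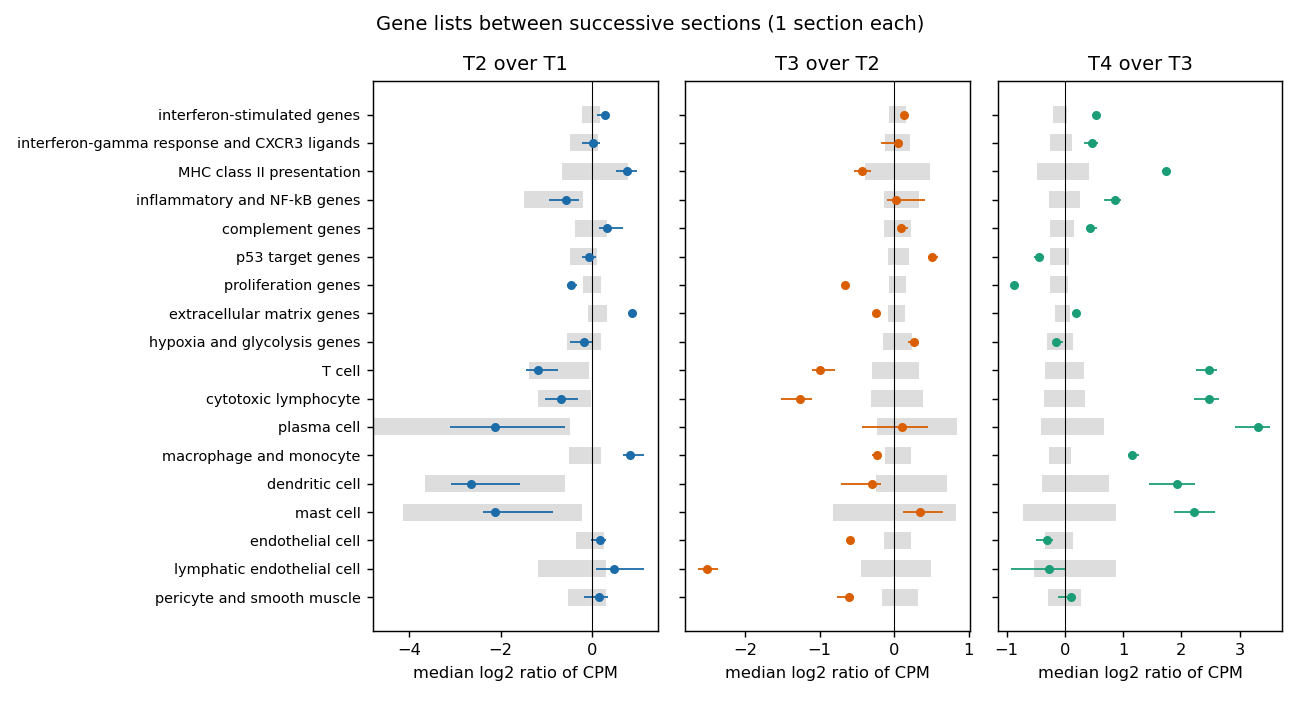
Median log2 ratio of CPM for 18 gene lists (vertical axis) between successive sections, 1 section each; points are medians, thin lines their 95% counting intervals, and grey bars the middle 95% of 10000 random lists of like expression. T cell and cytotoxic lymphocyte medians stand at -1.0 and -1.27 in T3 over T2 and at 2.47 each in T4 over T3, while the proliferation median lies left of the grey bar in all 3 panels.

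The second comparison, T3 over T2, asks what was different after radiation and a further dose. Genes induced by the tumour suppressor p53 were higher in T3, and proliferation, endothelial, pericyte, cytotoxic lymphocyte and most T cell genes were lower. Of 29 p53 target genes, 24 were higher, with a median of 0.51 (0.45 to 0.59), above all 10000 random lists, and of 0.30 over the 9 genes with a mean of at least 50 CPM. CDKN1A, the cyclin-dependent kinase inhibitor p21, stood at 27.5 CPM in T2 and 115 in T3, a ratio of 4.18 (3.90 to 4.48). The stress cytokine GDF15 had a ratio of 3.18 (2.92 to 3.47), the ferredoxin reductase FDXR 2.67 (2.33 to 3.06) and SPATA18, which acts in mitochondrial quality control, 7.54 (4.91 to 12) at a low level. Of 42 proliferation genes, 40 were lower, with a median of -0.66 (-0.70 to -0.61), below all 10000 random lists. The mitotic genes CDC20 (0.445, 0.409 to 0.485), CCNB1 (0.457, 0.431 to 0.485), CENPE (0.476, 0.443 to 0.510) and KIF20A (0.476, 0.440 to 0.516) led it. T3 was uneven in space: without the quadrant of T3 at low x and low y the proliferation median was -1.11, and without the quadrant at high x and high y it was -0.41.

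Vessel genes were lower in T3. Of 16 endothelial genes 15 were lower, with a median of -0.60 (-0.65 to -0.54), below all 10000 random lists. The tight junction gene CLDN5 stood at 126 CPM in T2 and 35.1 in T3 (ratio 0.279, 0.261 to 0.298), and KDR, the main receptor for VEGF, had a ratio of 0.491 (0.454 to 0.530). Of 7 lymphatic endothelial genes 6 were lower, with a median of -2.51 (-2.63 to -2.37), including the chemokine CCL21 (0.0901, 0.0667 to 0.119), the lymphatic transcription factor PROX1 (0.160, 0.138 to 0.184) and the receptor FLT4 (0.176, 0.158 to 0.194). The lymphatic genes of T2 were uneven in space. Without the quadrant of T2 at low x and low y, their median of T2 over T1 turned negative, at -0.61. The lower lymphatic level in T3 may thus depend on which part of the tumour T2 held. Pericyte and smooth muscle genes had a median of -0.61 (-0.76 to -0.54), with RGS5 at 0.303 (0.283 to 0.323) and NOTCH3 at 0.414 (0.408 to 0.419).

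Cytotoxic lymphocyte genes and most T cell genes were lower in T3 as well. Of 17 cytotoxic lymphocyte genes, 16 were lower, with a median of -1.27 (-1.51 to -1.11), and of 16 T cell genes, 13 were lower, with a median of -1.0 (-1.10 to -0.79). Both lay below all 10000 random lists. The granule genes GNLY (0.0978, 0.0797 to 0.119), CTSW (0.184, 0.151 to 0.224), NKG7 (0.241, 0.216 to 0.268) and GZMA (0.232, 0.193 to 0.277) led the first list, and the T cell receptor gene TRBC2 (0.323, 0.284 to 0.367) and the adhesion receptor CD2 (0.337, 0.287 to 0.395) the second. Limited to the 3 T cell genes with a mean of at least 50 CPM, the T cell median was 0.45, and the summed level of all T cell genes was 383 CPM in T2 and 422 in T3. That sum includes TRAC, which had 3723 UMIs in T2 and 4533 in T3. CD3D, CD3E, CD3G, CD2, TRBC1 and TRBC2 each had fewer UMIs in T3, such as 299 in T2 and 127 in T3 for CD3D. The summed level therefore leaned on TRAC. Macrophage genes were lower by less, with a median of -0.23 (-0.30 to -0.18) and 14 of 19 lower. SPP1, of the lipid-associated macrophage list, stood at 117 CPM in T2 and 10.5 in T3, a ratio of 0.0901 (0.0801 to 0.101). That list's summed level was higher in T3, at 2683 CPM against 2292 in T2.

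Interferon-stimulated genes differed little between T2 and T3, with a median of 0.13 (0.08 to 0.17), percentile 94.6. MX1, a GTPase that blocks viral replication, was higher (1.54, 1.47 to 1.62) and IFI44L lower (0.664, 0.631 to 0.699). Within the interferon-gamma list, whose median was 0.05 (-0.18 to 0.06), the ligands of the inhibitory receptor PD-1, PDCD1LG2 (3.07, 2.55 to 3.70) and CD274 (3.04, 2.44 to 3.79), were higher in T3, at 13.3 and 9.47 CPM. The checkpoint and exhaustion list, which also holds both, had a median of -0.51 (-0.61 to -0.33), with 12 of 17 genes lower, percentile 0.08. The secreted factors associated with senescence had a median of 0.54 (0.37 to 0.63), but -0.046 when limited to genes with a mean of at least 50 CPM. Heat shock and immediate early genes had a median of 0.35 (0.30 to 0.40), with the stress transcription factor ATF3 at 4.46 (3.88 to 5.13). Hypoxia and glycolysis genes had a median of 0.26 (0.18 to 0.33), while the glucose transporter SLC2A1 was lower (0.272, 0.247 to 0.299) and VEGFA higher (2.12, 1.99 to 2.27). Matrix genes had a median of -0.25 (-0.28 to -0.23), with lumican (LUM) at 0.360 (0.353 to 0.368) and tenascin C (TNC) at 2.73 (2.57 to 2.90). Among genes with at least 50 CPM in the higher section, ranked by the interval bound nearest to 1, the comparison was led by HS3ST2 (20.1, 16.9 to 24.0), a heparan sulfate sulfotransferase, the prostacyclin synthase PTGIS (11.1, 9.81 to 12.6), the lipocalin APOD (8.84, 8.33 to 9.38) and the microtubule-binding gene DCX (9.01, 8.18 to 9.95), and at the low end by FBN2, a microfibril gene (0.0586, 0.0506 to 0.0675). The mitochondrially encoded genes had a median of -0.47 (-0.49 to -0.47), with 10 of 11 lower, percentile 0.01.

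**Figure D2:**
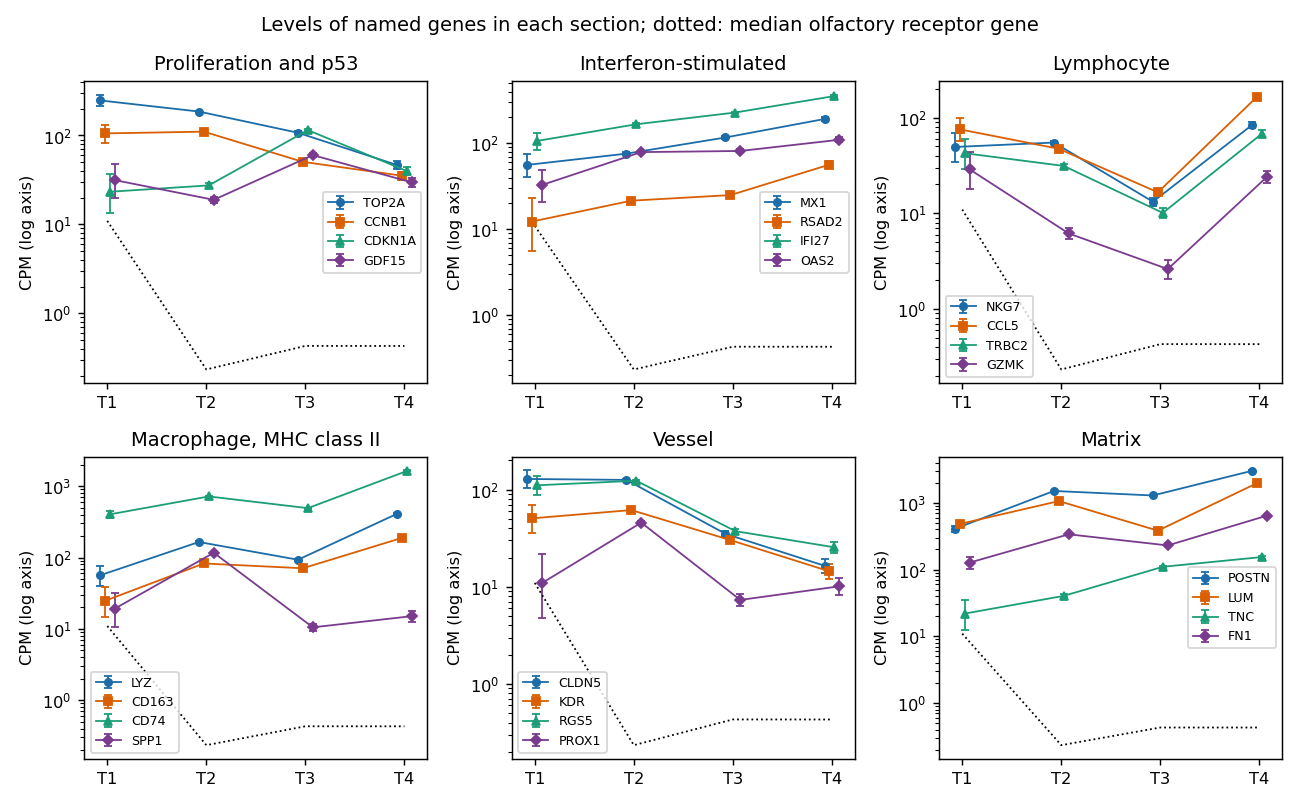
CPM (log axis) of 24 named genes in sections T1 to T4, 1 section each, in 6 panels by gene group; bars are exact Poisson 95% intervals and the dotted line is the median olfactory receptor gene. TOP2A was lower in each later section, CDKN1A was highest in T3, and NKG7, CCL5, TRBC2 and GZMK were lowest in T3.

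The third comparison, T4 over T3, asks what was different in the surgical tumour after the third dose. Cytotoxic, T cell, plasma cell, macrophage and class II presentation genes were higher in T4, proliferation genes were lower again, and p53 target genes were lower than in T3. The 17 cytotoxic lymphocyte genes had a median of 2.47 (2.21 to 2.65), with 16 higher, and the 16 T cell genes a median of 2.47 (2.25 to 2.62), with 15 higher, each above all 10000 random lists. The T cell attractant CCL5 stood at 16.6 CPM in T3 and 165 in T4, a ratio of 9.94 (8.98 to 11). The granzyme gene GZMK (9.17, 7.06 to 12) and the receptor KLRB1 (8.81, 7.02 to 11.1) were higher by like amounts. The regulatory T cell list had a median of 1.45 (1.05 to 1.77), led by its transcription factor FOXP3 (4.98, 3.08 to 8.17), while TNFRSF4 was lower (0.360, 0.311 to 0.415). The list's summed level was lower, at 59.0 CPM in T4 against 82.2 in T3. In T3, TNFRSF4 was a leading gene of an unnamed cluster, with 973 UMIs there, against 2482 UMIs of the whole list in that section. The summed level therefore need not follow regulatory T cells. Checkpoint and exhaustion genes had a median of 0.45 (0.34 to 0.67), with the inhibitory receptor TIGIT at 7.81 (5.87 to 10.5) and CD96 at 7.69 (6.19 to 9.62).

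Antibody genes were higher in T4. The 10 plasma cell genes had a median of 3.32 (2.91 to 3.51), with 7 higher, above all 10000 random lists. The kappa light chain gene IGKC stood at 24.0 CPM in T3 and 238 in T4 (ratio 9.88, 9.08 to 10.8), the heavy chain gene IGHM had a ratio of 43.4 (23.6 to 88.8) and the joining chain gene JCHAIN one of 21.2 (14.6 to 31.8). B cell genes, at 0.48 (0.07 to 0.93), did not stand outside the middle 95% of random lists, and genes of tertiary lymphoid structures had a median of 1.17 (0.79 to 1.38). Mast cell genes had a median of 2.22 (1.87 to 2.58), led by the histamine-forming enzyme HDC (7.26, 5.51 to 9.65) and the protease CPA3 (6.40, 5.29 to 7.76).

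Macrophage and class II presentation genes were higher too. Of 19 macrophage and monocyte genes 18 were higher in T4, with a median of 1.16 (1.08 to 1.27), above all 10000 random lists. LYZ had a ratio of 4.41 (4.20 to 4.63), the Fc receptor FCGR3A 3.93 (3.55 to 4.36) and the complement gene C1QC 2.98 (2.85 to 3.11). Lipid-associated macrophage genes had a median of 0.51 (0.27 to 0.66), with 8 of 12 higher, but their summed level was lower, at 2520 CPM in T4 against 2683 in T3, and the median was -0.29 over genes with a mean of at least 50 CPM. The 3 class II presentation genes were all higher, with a median of 1.73 (1.66 to 1.76), among them the invariant chain CD74 (3.32, 3.25 to 3.40) and CIITA, the master regulator of class II genes (3.49, 3.16 to 3.84). Dendritic cell genes had a median of 1.93 (1.45 to 2.24) and plasmacytoid dendritic cell genes one of 2.11 (1.72 to 2.47), with LILRA4 at 18.6 (9.72 to 39.1), while the summed dendritic cell level was 236 CPM in T3 and 242 in T4. Complement genes had a median of 0.43 (0.37 to 0.55), inflammatory and NF-kB genes one of 0.87 (0.68 to 0.97), led by the chemokines CCL4 (7.13, 5.65 to 9.03) and CCL3 (6.62, 4.68 to 9.49), and neutrophil genes one of 1.03 (0.40 to 1.33), although their summed level was lower, at 239 CPM in T4 against 265 in T3. Interferon-stimulated genes had a median of 0.54 (0.50 to 0.59), with 34 of 40 higher, above all 10000 random lists, led by IFI44L (2.17, 2.03 to 2.32), the antiviral enzyme RSAD2 (2.26, 2.02 to 2.53) and SAMD9 (2.11, 1.96 to 2.27). Interferon-gamma response genes had a median of 0.47 (0.32 to 0.57), with the transcription factor IRF8 at 4.16 (3.72 to 4.66) and the tryptophan-degrading enzyme IDO1 at 3.97 (3.44 to 4.57). The 13 class I presentation genes did not follow, with a median of -0.06 (-0.10 to 0.00), and the genes of double-stranded RNA sensing, at 0.12, percentile 95.5, did not stand apart.

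All 42 proliferation genes were lower in T4 than in T3, with a median of -0.87 (-0.93 to -0.78), including the nucleotide synthesis genes RRM2 (0.392, 0.326 to 0.468) and TYMS (0.428, 0.361 to 0.505) and the topoisomerase TOP2A (0.434, 0.392 to 0.480). Of 29 p53 target genes 24 were lower, with a median of -0.45 (-0.52 to -0.35), and CDKN1A had a ratio of 0.347 (0.310 to 0.386). Matrix genes were higher by a small margin, with a median of 0.20 (0.18 to 0.21) and 24 of 32 higher, percentile 99.98. LUM (5.14, 5.02 to 5.26), fibronectin (FN1, 2.79, 2.70 to 2.89) and POSTN (2.34, 2.31 to 2.38) led them. Endothelial genes were lower again, with a median of -0.31 (-0.49 to -0.21), including the VEGF receptors FLT1 (0.373, 0.307 to 0.450) and KDR (0.477, 0.395 to 0.572). The immediate early genes FOS and DUSP1 had ratios of 6.85 (6.17 to 7.63) and 3.52 (3.40 to 3.65). The list that holds them together with heat shock genes had a median of -0.15 (-0.23 to -0.09). Its summed level was higher, at 2667 CPM in T4 against 2333 in T3. CCN1, a matrix protein that responds to mechanical load, stood at 100 CPM in T3 and 701 in T4, a ratio of 6.98 (6.68 to 7.29). DCX (0.0820, 0.0652 to 0.102), APOD (0.109, 0.0969 to 0.122) and HS3ST2 (0.0955, 0.0731 to 0.123), which had been among the highest in T3 over T2, were among the lowest in T4 over T3.

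The whole course, T4 over T1, asks how the tumour at surgery differed from the untreated one. Interferon-stimulated genes had a median of 0.80 (0.70 to 0.93), with 37 of 40 higher, above all 10000 random lists, led by IFI27 (3.33, 2.66 to 4.22), MX1 (3.42, 2.51 to 4.78), RSAD2 (4.59, 2.40 to 10.1) and IFI6 (2.79, 2.36 to 3.32). The cytotoxic lymphocyte list had a median of 0.35 (-0.01 to 0.68) against -0.44 for random lists, percentile 99.9, with 10 genes higher and 7 lower. CCL5 (2.18, 1.67 to 2.91) and FCGR3A (9.22, 4.46 to 23.0), which the macrophage list also holds, were higher. IFNG, the interferon gamma gene, had 46.6 CPM in T1 and 1.61 in T4 (0.0346, 0.0175 to 0.0653), and its 34 UMIs in T1 were fewer than the 41 of the highest olfactory receptor gene there. With the olfactory receptor median subtracted, the cytotoxic median was 1.09, at percentile 94.8. All 19 macrophage genes were higher, with a median of 1.70 (1.61 to 2.26), and matrix genes had a median of 0.98 (0.89 to 1.04), with POSTN at 7.40 (6.60 to 8.32). Complement genes had a median of 1.15 (0.92 to 1.48), with the classical pathway protease C1R at 9.46 (6.65 to 13.9). All 42 proliferation genes were lower, with a median of -2.02 (-2.13 to -1.83), and UBE2C stood at 149 CPM in T1 and 14.5 in T4. Endothelial genes had a median of -0.89 (-1.07 to -0.58), with CLDN5 at 0.128 (0.0982 to 0.167). Pericyte genes had one of -1.08 (-1.38 to -0.39), which became 0.46 with the olfactory receptor median subtracted.

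T3 over T1 compares the irradiated with the untreated tumour. Proliferation genes had a median of -1.21 (-1.28 to -1.06), with all 42 lower, and matrix genes one of 0.71 (0.64 to 0.78). Macrophage genes had a median of 0.70 (0.48 to 0.96), with 16 of 19 higher. CDKN1A had a ratio of 4.93 (3.08 to 8.48), while the p53 target list had a median of 0.12 (0.11 to 0.63), percentile 91.6. Interferon-stimulated genes had a median of 0.20 (0.14 to 0.40), percentile 92.8. With the olfactory receptor median subtracted, both stood apart from random lists, p53 targets at 1.04, percentile 99.9, and interferon-stimulated genes at 0.69, percentile 99.8. Cytotoxic lymphocyte genes had a median of -2.20 (-2.48 to -1.79) against -1.14 for random lists, percentile 1.26.

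Shares of segments were compared at 1 depth, with each segment thinned to 50 UMIs. Macrophage and monocyte genes then gave a UMI in 3.38% (2.95 to 3.85) of T1 segments, 7.59% (7.14 to 8.05) in T2, 6.51% (6.15 to 6.89) in T3 and 15.2% (14.5 to 15.9) in T4, with exact binomial intervals. Cytotoxic lymphocyte genes gave one in 1.89% (1.57 to 2.25), 1.56% (1.35 to 1.78), 0.516% (0.414 to 0.636) and 3.11% (2.76 to 3.48). T cell genes gave one in 2.72% (2.34 to 3.14), 2.03% (1.80 to 2.29), 2.22% (2.00 to 2.45) and 3.06% (2.72 to 3.44), so that this share was not lower in T3 than in T2 at that depth. With 100 UMIs per segment the order turned, at 3.97% (3.64 to 4.32) in T2 and 3.77% (3.49 to 4.07) in T3. With 200 UMIs it was 7.54% (7.09 to 8.01) in T2 and 8.47% (8.06 to 8.90) in T3. These shares include TRAC, which had 3723 UMIs in T2 and 4533 in T3. Proliferation genes gave one in 15% (14.1 to 15.9), 11.5% (10.9 to 12), 6.41% (6.04 to 6.78) and 4.12% (3.72 to 4.54). Olfactory receptor genes, as many as in the cytotoxic list, gave one in 0.998% of T1 segments and in at most 0.0528% of segments in the other sections. Without thinning, macrophage genes gave a UMI in 5.05% of T1 segments and in 79.9%, 75.2% and 78.8% of those in T2, T3 and T4.

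**Figure D3:**
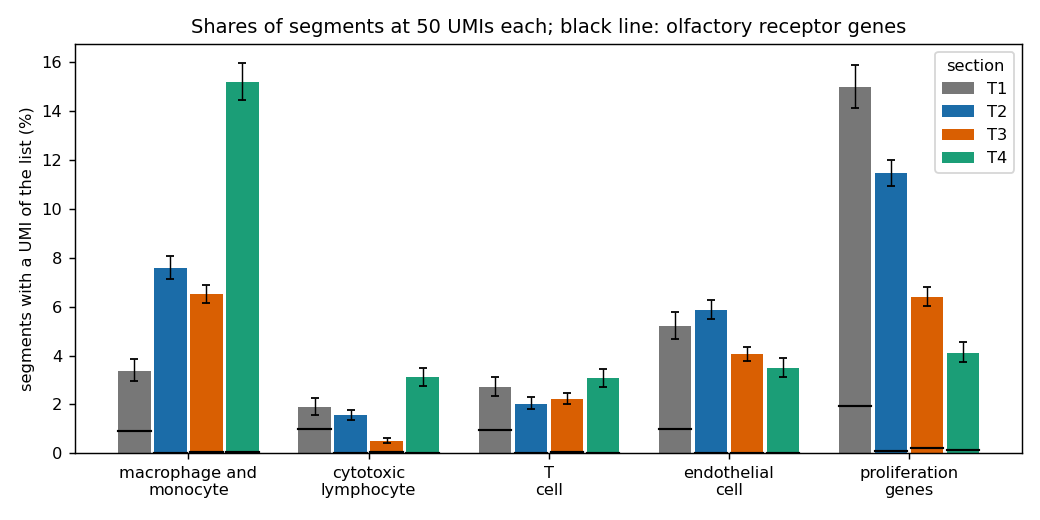
Percent of segments with at least 1 UMI of a gene list after each segment was thinned to 50 UMIs, in sections T1 to T4 (colours); error bars are exact binomial 95% intervals and black lines give the share for as many olfactory receptor genes. Macrophage genes reach 15.2% in T4, proliferation genes range from 15% in T1 to 4.12% in T4, and the cytotoxic share is lowest in T3 at 0.516%.

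Clustering of all segments with at least 50 UMIs gave 19 clusters, of which most held 1 section almost alone. Named by their leading genes, macrophage-like clusters held 12.5% (11.9 to 13.0) of T2 segments, 0.153% (0.0997 to 0.223) of T3 and 22.5% (21.7 to 23.4) of T4. Endothelial-like clusters held 13.9% (13.3 to 14.5) of T2, 6.09% (5.74 to 6.46) of T3 and 3.31% (2.96 to 3.70) of T4. A lymphatic endothelial-like cluster held 8.78% (8.30 to 9.27) of T2, 0.176% (0.119 to 0.251) of T3 and 1.84% (1.58 to 2.14) of T4. The cytotoxic-like cluster, led by the chemokines CXCL10, CXCL11 and CXCL9, held 2.98% (2.69 to 3.28) of T2, 0.252% (0.183 to 0.340) of T3 and 0.401% (0.282 to 0.552) of T4. No cluster of T1 was named at this setting, while at resolution 2 a cluster named endothelial-like, with a median of 82 UMIs, held 49.2% of T1 segments. These shares depended on the clustering. Endothelial-like clusters held less of T2 than of T3 with at least 100 UMIs per segment (0.540% and 3.72%) and at resolution 2 (6.95% and 10.8%). At both settings a cluster with RBP7 and FLT1 among its leading genes stayed unnamed, with 2202 and 1780 segments of T2. With at least 100 UMIs an unnamed cluster led by CHST1 and APLN also held 940 segments of T3. The order of these shares therefore rests on which clusters received the name. The lymphatic endothelial-like share of T4 was 0.0333% with at least 200 UMIs per segment and 0.0325% at resolution 2, below those of T3 (0.0474% and 0.0469%). The cytotoxic-like share of T4 was 2.21% with at least 200 UMIs per segment and 3.26% at resolution 2, where it exceeded the 2.91% of T2. The macrophage-like share of T3 was 2.00% at resolution 2, and no cluster was named macrophage-like at resolution 0.5. At resolution 2 a cluster named plasma cell-like, by IGHA1, IGKC and IGHG1 alone, held 31.3% of T4 segments. At resolution 1 no cluster had that name, and IGHA1 and IGKC led an unnamed cluster with 6196 of the 9234 clustered T4 segments. Some of these shares went apart from the gene levels. Macrophage genes summed to 1386 CPM in T2 and 1328 in T3, with a UMI in 7.59% and 6.51% of segments thinned to 50 UMIs. The macrophage-like clusters lay to 96.1% in T4 and to 95.1% in T2, so their low share in T3 need not mean fewer macrophages. Cytotoxic lymphocyte genes summed to 299 CPM in T2 and 609 in T4. Segments can hold transcripts of neighbouring cells, and the shares of segments with a UMI at equal depth do not rest on the clusters.

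Levels near T cells were compared with levels farther away, within and beyond 50 micrometres of segments with a T cell marker UMI. With the 7 fixed marker genes, interferon-stimulated genes were higher near than far in T3 (ratio 1.15, 1.13 to 1.17) and T4 (1.16, 1.14 to 1.19) and not in T2 (0.984, 0.961 to 1.01). In T4 the T cell attractants CXCL9 (3.42, 1.47 to 8.58), CXCL10 (2.44, 1.81 to 3.31) and CXCL11 (2.29, 1.03 to 5.27) were higher near T cell marker segments, and macrophage genes were too (1.18, 1.14 to 1.21). In T3, CXCL10 was not (0.844, 0.628 to 1.15), and proliferation genes were higher near (1.56, 1.51 to 1.61). TRAC gave 38.3% of the marker UMIs in T1, 54.1% in T2, 82.3% in T3 and 36.1% in T4, unlike the other 6 genes. Without TRAC, an alternative chosen after seeing the data, CXCL10 was higher near than far in T2 (3.62, 2.63 to 5.09), T3 (2.38, 1.95 to 2.91) and T4 (3.48, 2.64 to 4.62), and interferon-stimulated genes were higher in T2 (1.11, 1.10 to 1.13), T3 (1.32, 1.30 to 1.34) and T4 (1.27, 1.24 to 1.29). Deeper segments reveal a T cell UMI more often: without TRAC the near segments of T3 had a median of 1866 UMIs and the far ones 1343. An unnamed cluster of T3 with KIF20A, CDC20 and ASPM among its leading genes had a median of 2473 UMIs, against 1474 in the section. The proliferation ratio of 1.56 in T3 therefore carries the same limit.

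**Figure D4:**
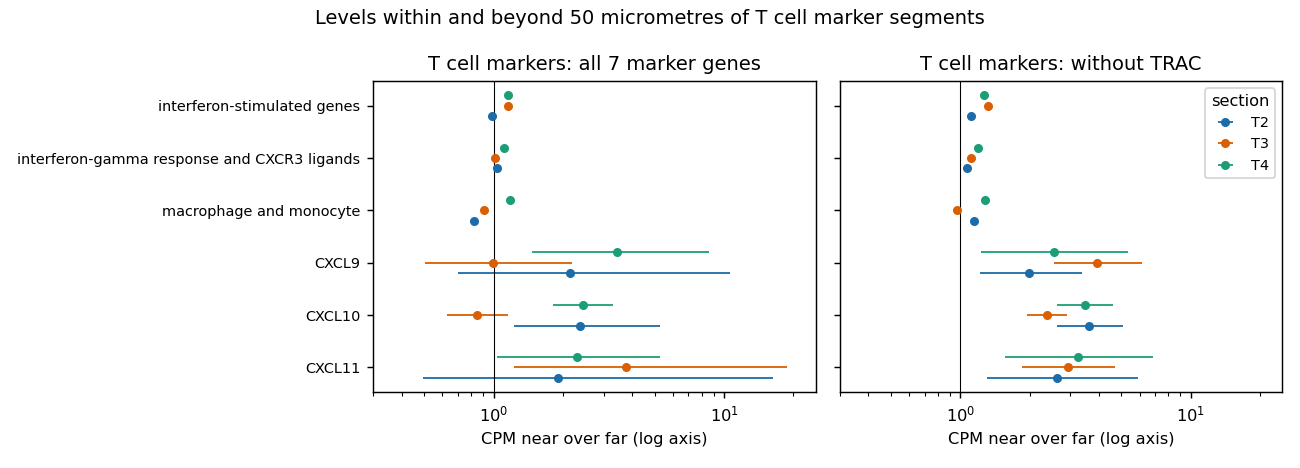
Ratio of CPM in segments within 50 micrometres of a T cell marker segment over that in segments beyond it (log axis), for 3 gene lists and 3 chemokine genes in T2, T3 and T4 (colours), with 7 marker genes on the left and without TRAC on the right; lines are exact 95% counting intervals. Without TRAC, CXCL10 has ratios of 3.62, 2.38 and 3.48.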

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

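The background subtraction, the filter at a mean of 50 CPM and the distances without TRAC were chosen after seeing the data, and the other alternatives were planned. The 8 list medians that answer the planned comparisons gave 95 values under the alternatives, of which 65 stayed within the counting interval, 30 moved past it and 0 reversed. A value could count as reversed only if the reported interval excluded no change and, for a list, the list also stood apart from random lists. The interferon-gamma median of T2 over T1 and the cytotoxic median of T4 over T1 did not meet this rule. The interferon-gamma median of T2 over T1, 0.03 as reported, did not stand apart from random lists and ranged from -0.10 to 0.48. Its sign thus changed without being counted. With TMM the medians were 0.72 (interferon-stimulated, T2 over T1), 0.48 (interferon-gamma, T2 over T1), 0.40 (p53 targets, T3 over T2), -0.76 (proliferation, T3 over T2), 0.23 (matrix, T4 over T3), 1.18 (interferon-stimulated, T4 over T1) and 0.73 (cytotoxic, T4 over T1). Size factors gave 0.72 and 0.48 for the first pair, 0.23 for matrix, and 1.25 and 0.80 for the last pair. These factors shift all genes of a comparison by 1 amount, as their construction shows. Without mitochondrial and top 50 genes in the totals, proliferation gave -0.70 and matrix 0.23. With the background subtracted, interferon-stimulated genes gave 0.66 (T2 over T1) and 1.16 (T4 over T1), interferon-gamma 0.37 and cytotoxic 1.09. Limited to genes with a mean of at least 50 CPM, p53 targets gave 0.30 and macrophage genes (T4 over T3) 1.28, and the cytotoxic list had no value for T4 over T1. With 1 quadrant of a section left out, the medians reached 0.15 and 0.39 (interferon-stimulated, T2 over T1), 0.35 and 0.64 (p53 targets), -1.11 and -0.41 (proliferation), 0.15 and 0.25 (matrix), 1.03 and 1.27 (macrophage) and 0.67 (interferon-stimulated, T4 over T1). Of 1999 values of the other 177 list medians, 1548 stayed within the interval, 443 moved and 8 reversed. Lymphatic endothelial genes (T2 over T1) reached -0.61 without 1 quadrant of T2. With the 50 CPM filter, senescence (T3 over T2) gave -0.046, T cell (T3 over T2) 0.45, lipid-associated macrophage (T4 over T3) -0.29 and pericyte genes (T4 over T1) 0.35. With the background subtracted, pericyte genes (T4 over T1) gave 0.46 and endothelial genes (T3 over T1) 0.16, and with no UMI filter plasma cell genes (T4 over T1) gave -0.089. The filters leave fewer or weaker genes in a list, and otherwise the cause was not tested. Of 168 near over far ratios, 98 stayed within the interval, 62 moved and 8 reversed. Without TRAC these were 1.15 (macrophage), 0.988 (p53 targets) and 1.03 (endothelial) in T2 and 1.01 (proliferation) in T4. At 100 micrometres they were 0.999 (matrix, T3), 1.12 (proliferation, T4) and 1.02 (matrix, T4), and at 25 micrometres 1.07 (proliferation, T4). The cause was not tested. Of 469 values of 118 named gene ratios, 403 stayed within the interval, 66 moved and 0 reversed. Shares of segments with a UMI rose with depth by construction, and 119 of 120 values moved. Of 68 cluster shares 38 moved, among them the endothelial-like shares of T2 and T3, whose order turned at 100 UMIs per segment and at resolution 2. Genes with zero UMIs in 1 section, put at 3 counts, moved 5 of 185 list medians by over 0.1. No paired analysis was possible because each time point had 1 section of the same tumour. The depth of T1 limits all ratios against it, and a gene below 32.9 CPM there lay within 3 times the olfactory receptor median.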

Other observations

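The test of endothelial genes against a lower share of the most abundant cell type was chosen after its result was seen, as were the comparisons within cluster classes, and the rules for reading both tests of the T1 background were made stricter after their values were seen. All patterns below were found and tested on the same 4 sections, so each is a hypothesis.

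Macrophage-like segments of T4 and T2 were compared by their interferon-stimulated genes. Among 2082 segments of T4 and 1649 of T2 these had a median log2 ratio of 0.80 (0.71 to 0.88), and MX1 stood at 320 CPM in T4 and 110 in T2. The class was made up of 2 clusters, of which 1 held 2013 of the T4 segments and the other 1581 of the T2 segments. The comparison is therefore one of separately defined clusters, and their leading genes, such as SPP1 in T2 and CXCL10 and CIITA in T4, helped to define them. The same segments of T4 also had higher T cell genes, at 1.88, plasma cell genes, at 5.61, and mast cell genes, at 4.27, none of which macrophages make in quantity. Whether these came from neighbouring cells or from other cells placed in the cluster was not tested, and the part of the interferon signal that belongs to the macrophages was not separated.

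p53 target genes differed more in endothelial-like segments than in unnamed clusters between T2 and T3. The class was made up of 2 clusters with different leading genes, of which 1 held 1828 of its 1845 T2 segments and the other 1004 of its 1038 T3 segments, and both its size and its members depended on the clustering. The unnamed segments of T2 and T3 also lay in different clusters for the most part, so neither class was followed as 1 group. In T3 over T2, p53 target genes had a median of 1.09 (0.88 to 1.24), against 0.61 (0.51 to 0.66) in unnamed clusters. CDKN1A stood at 266 CPM in T3 and 26.3 in T2 in endothelial-like segments (ratio 10.1, 8.25 to 12.4), and GDF15 had a ratio of 14.6 (10.4 to 21.1). Proliferation genes had a median of -1.93 (-2.12 to -1.74) there, against -0.68 in unnamed clusters. Interferon-stimulated genes were lower in endothelial-like segments of T3, at -0.22 (-0.34 to -0.13), and higher in unnamed clusters, at 0.34 (0.29 to 0.38). In T4 over T2, with 306 endothelial-like segments in T4, interferon-stimulated genes had a median of 0.42 (0.23 to 0.51) and class II presentation genes one of 1.44 (1.21 to 1.56). Which cells make up the unnamed clusters was not determined.

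Lymphocyte genes were lower in T3 and higher in T4, by list medians and, for cytotoxic genes, by shares of segments. The summed T cell level was not lower in T3. The T cell share was not lower there at 50 or 200 UMIs per segment, but was 3.97% in T2 and 3.77% in T3 at 100. Both measures include TRAC, with 3723 UMIs in T2 and 4533 in T3. The other T cell marker genes used for distances each had fewer UMIs in T3. A lower share of the most abundant cell type in T4 would have raised the genes of every other type alike. In T4 over T3 the cytotoxic median was 2.47, the mast cell median 2.22 and the macrophage median 1.16, while the pericyte median was 0.11 (-0.11 to 0.19) and the endothelial median -0.31 (-0.49 to -0.21). Types that moved apart by this much argue against that explanation as the whole cause, and a change in the immune cells as a group stays open. Had the lymphocyte genes of T4 lain in 1 quadrant, leaving that quadrant out would have taken the cytotoxic median below 0.5 times its value of 2.47. The lowest value with a quadrant of T3 or T4 left out was 2.22, so no single quadrant of T4 carried the difference. For T3 this cannot decide, since leaving out a quadrant of T3 rich in these genes would raise the median. What stays open is a lymphocyte increase after the third dose or after the end of radiation, the place from which each piece of tumour was taken, and the handling of each section. These cannot be told apart with 1 section per time point, and a radiation-related loss of lymphocytes in T3 with later recovery is consistent with the same values.

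Proliferation genes had a lower list median in each later section, but in T2 over T1 that median was -0.01 with TMM, so the tests concern the later steps. A change in the mix of named cell classes predicts a small difference within the unnamed clusters, but the proliferation median of T4 over T2 there was -1.71 (-1.77 to -1.60). A few genes taking a growing share of the UMIs predicts a value nearer to 0 once they are left out of the totals. Without the mitochondrial genes and the 50 genes with most UMIs, the median of T4 over T3 was -0.83. The first value argues against that explanation for T4 over T2 and the second for T4 over T3, and the step from T1 to T2 was not tested. A treatment effect may account for the pattern, but the place of each piece within the tumour and a change in the mix of cells within the unnamed clusters remain open, and leaving out 1 quadrant of T3 took the median of T3 over T2 as far as -1.11 and -0.41.

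Silent genes were higher in T1. Olfactory receptor UMIs numbered 543 per square millimetre of occupied area in T1, 411 in T2, 338 in T3 and 116 in T4, while all UMIs numbered 119378, 3663390, 1908450 and 586731. A level of nonspecific UMIs set by area, not by RNA, predicts that segments of T1 with more other UMIs per area hold no more olfactory receptor UMIs per area. The ratio between segments above and below the median was 1.51 (1.41 to 1.62), against 1.88 for the other UMIs. It met the bound set in advance, below 1.88, but also exceeded 1, so a part set by area and a part that follows RNA are both consistent with it. Expression of these genes by cells would make single genes stand out. The variance over the mean of UMIs across the 348 genes was 4.80 (4.06 to 5.65) in T1, below the bound of 10 set in advance for expression. The bound set against it, 5, lies within that interval, so expression gained no support and was not excluded either. The same quantity was 11.9 in T2, 28.7 in T3 and 4.39 in T4. If all genes had the median olfactory receptor level as background, it would make up 19.8% of T1 UMIs and 0.423%, 0.778% and 0.777% of those in T2, T3 and T4.

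Lists of cell types outside the planned questions were also read. In T2 over T1 the Schwann cell median was -3.23 (-3.68 to -2.54), at percentile 1.11. With the olfactory receptor median subtracted it was -2.47 over the same genes and 0.38, at percentile 33.1, over the 6 that then had enough UMIs. The medians of T2 over T1 were -1.14 for skeletal muscle, -1.15 for adipocyte, -1.74 for epithelial and -3.44 for red blood cell genes, all within the middle 95% of random lists. In T4 over T3 they were 0.29 for Schwann cell, 0.45 for skeletal muscle, -0.40 for adipocyte, -0.56 for epithelial and -0.48 for red blood cell genes, of which the epithelial list, at percentile 1.37, lay outside it. Housekeeping genes had medians of 0.21 (0.12 to 0.37) in T2 over T1 and -0.17 (-0.25 to -0.13) in T4 over T3, and mitochondrially encoded genes -0.06 in T4 over T3. With genes that had zero UMIs in 1 section put at 3 counts, the adipocyte median of T3 over T1 went from -0.40 to -1.32, and the interferon-gamma medians against T1 went to -0.05 (T2), -0.18 (T3) and 0.28 (T4).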
